A study of Arabidopsis thaliana with 8 samples.

How the data were processed

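RNA from shoot apices of Arabidopsis thaliana seedlings of the Landsberg erecta (Ler) background was profiled on 1-colour Affymetrix arrays, 1 biotin-labelled total RNA sample per array, at 14 days after sowing under short days. The 8 arrays fall into 3 groups by their titles: 4 wild-type arrays, 2 arrays of the fil yab3 mutant and 2 arrays of the fil yab3 yab5 mutant. The labels do not say whether arrays of a group came from separate batches of plants, so p-values measure only the spread between these samples, which may be technical.

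The authors deposited a log2 value for each probe set, computed with GCRMA in R 2.7.2 per the submitters' processing notes. GCRMA corrects the background with a model of probe sequence, normalizes arrays by quantiles and summarises the probes of a set. The settings used are not given in the sources used here. The log2 scale was read from the values, which run from a shared lowest value of about 2.1 to at most 15.8. Many dim probe sets sit at that floor on all arrays of a group, so their differences have no measured lower end. Such arrays also show no spread, which lowers the spread estimated by the fit and the p-values of these probe sets.

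The table holds 22810 rows. After 64 Affymetrix control probe sets were set aside, 22746 probe sets remained, and 13888 with a log2 value above 4 on at least 2 arrays were tested. Gene names came from a platform annotation whose gene identifiers were matched to the TAIR10.1 gene table, which was used for names and gene order only. Of the 13888 tested probe sets, 7512 name 1 gene, 278 name several and 6098 are unnamed here. Genes without a named probe set, FIL among them, are not analysed here. A gene with several probe sets was represented by the one with the highest mean over all arrays, which left 7433 named genes.

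Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited values. All 8 arrays were fitted as 3 groups with 5 residual degrees of freedom. The wild-type arrays fell into pairs, described below, and this fit counts the shift between the pairs as spread. It called 23 probe sets for fil yab3 and 538 for fil yab3 yab5 against wild type, and 94 between the mutants. With the pairs fitted as separate groups these counts were 332, 2484 and 233. The counts are therefore no measure of the size of the mutant effects. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Each fold change is given as a log2 difference with its standard error (SE) from the fit. Where all arrays of one group lay at or below a log2 value of 4, a lower bound is given, the brighter group's mean against that level, and written as at least N-fold.

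Before the data were examined, 37 gene lists with 534 genes were fixed, covering YABBY and polarity genes, meristem, hormone, growth and metabolic genes, and markers of other organs, handling and harvest time. Only 82 of these genes have a named probe set and 67 were tested. The 10 lists with at least 3 tested genes were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation. After the gene names had been read, and before their fold changes were computed, families sharing a symbol prefix were added.

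The genes named are the YABBY genes, the 10 most raised and 10 most lowered genes of each mutant against wild type (5 and 5 for the mutants against each other), and members of the lists. The most raised and most lowered genes had to pass the threshold on a probe set naming 1 gene, with no overlap between the arrays of the groups. Of each list, up to 4 members that passed are named, or up to 2 as values where none passed.

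Alternatives set before the data were examined were no filter on dim probe sets, a filter at a log2 value of 6, quantile normalization, median centring, an intensity trend with robust estimation, array weights, a fit of only the groups compared, removal of probe sets that can match several genes, a replicate block, other set tests and leaving out each array. Fits with other choices of wild-type arrays, and fits that leave out 1 array but keep the probe sets tested with all 8, were added after seeing the data. The fit was tested on simulated data with 200 of 13888 probe sets changed. For fil yab3 against wild type it called 20% of probe sets changed by 1 log2 unit, 62% of those changed by 2 and 94% of those changed by 4. For fil yab3 yab5 against wild type the shares were 14%, 58% and 86%. Of the calls, 6.8% and 5.3% were false in these 2 comparisons. The simulated noise was independent on every array, without wild-type pairs or a floor, so these shares may not hold for the measured data. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.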

Results

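The series measured transcripts in shoot apices of 14-day-old Arabidopsis seedlings to compare wild type with plants that lack several YABBY genes, a family of transcription factors known for roles in leaf lamina growth and abaxial identity. Wild type was measured on 4 arrays, the fil yab3 mutant (called the double mutant here) on 2 and the fil yab3 yab5 mutant (the triple mutant) on 2. Median log2 signals were close, from 5.74 to 5.88, and 58.2% to 58.8% of probe sets lay above a log2 value of 4 on each array. GCRMA normalizes by quantiles, so this closeness does not show that the arrays are alike.

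The wild-type arrays fell into pairs. Pearson's r across tested probe sets was 0.970 between arrays 1 and 2 and 0.970 between arrays 3 and 4, but 0.861 to 0.888 between the pairs. The mutant arrays correlated with wild-type arrays 3 and 4 at 0.913 to 0.956 and with arrays 1 and 2 at 0.850 to 0.914. All 42 spike-in control probe sets, which detect bacterial and phage transcripts, were higher on wild-type arrays 1 and 2 than on every other array, by a median of 2.73 log2 units. Plastid-encoded genes were higher on arrays 1 and 2 than on arrays 3 and 4, by a median of 7.52 log2 units over 68 probe sets. So were mitochondrial genes, by a median of 6.77 over 3 probe sets. Because the other 6 arrays share the low spike-in signals, values against wild-type arrays 3 and 4 are given beside the pooled ones where counts are compared. Probe sets near the 3′ end exceeded those near the 5′ end of control transcripts by a mean of 1.29 and 1.44 log2 units on wild-type arrays 1 and 2 and by 1.41 on double mutant array 1, against 0.501 and 0.466 on wild-type arrays 3 and 4, 0.593 on double mutant array 2 and 0.732 and 0.599 on the triple mutant arrays.

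**Figure D1:**
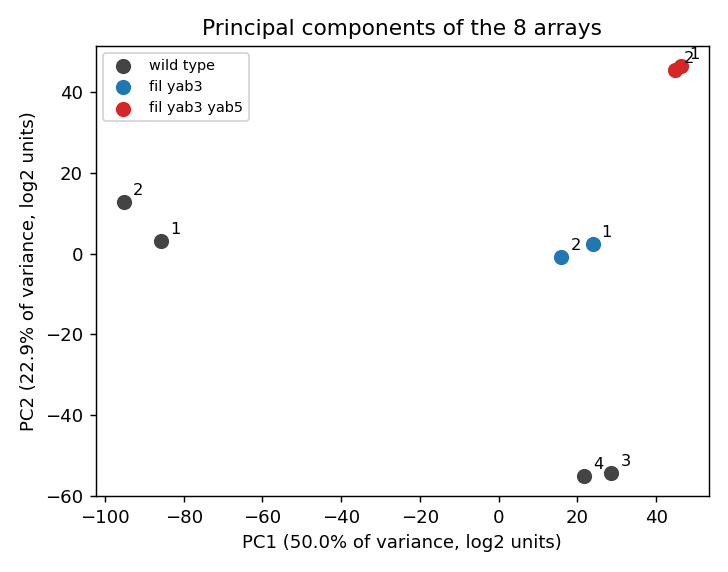
Principal components of the 13888 tested probe sets, each point 1 array numbered by replicate; the x axis is the first component (50% of variance) and the y axis the second (22.9%), both in log2 units. Wild-type arrays 1 and 2 lie at -85.7 and -95.2 on the first component, and the other 6 arrays between 15.9 and 46.2.

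The targeted genes were examined first. YAB3 signal was 8.80 ± 0.51 (SD, n = 4) in wild type, 4.17 ± 1.16 (n = 2) in the double mutant and 4.95 ± 0.78 (n = 2) in the triple mutant. It fell by 4.63 ± 0.55 (SE) log2 units in the double mutant (limma adjusted p = 0.033) and by 3.85 ± 0.55 in the triple mutant (adjusted p = 0.013). YAB5 signal was 6.38 ± 1.13 in wild type, 5.82 ± 0.31 in the double mutant and 5.15 ± 0.18 in the triple mutant, and its difference in the triple mutant, -1.23 ± 0.66, did not pass (adjusted p = 0.358). That YAB5 difference was -2.20 against wild-type arrays 1 and 2 (adjusted p = 0.0042) and -0.26 against arrays 3 and 4 (adjusted p = 0.490), so YAB5 signal alone does not tell the triple mutant from wild type. Whether the YAB5 probe set lies outside the mutated part of the gene is not given in the sources used here. INO, a YABBY gene of ovules, was too dim in all groups to be tested. The YAB3 call in the double mutant was lost against wild-type arrays 3 and 4 alone (-5.03, adjusted p = 0.065) and without any 1 of the 8 arrays. The difference was -3.81 without double mutant array 1 and -5.45 without array 2. Without either triple mutant array it stayed at -4.63, so there only the estimated spread and the adjustment changed. YAB3 lay at 5.50 or below on every mutant array and at 8.35 or above on every wild-type array. In the triple mutant the YAB3 call was lost without triple mutant array 1 (-3.30) or array 2 (-4.41).

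**Figure D2:**
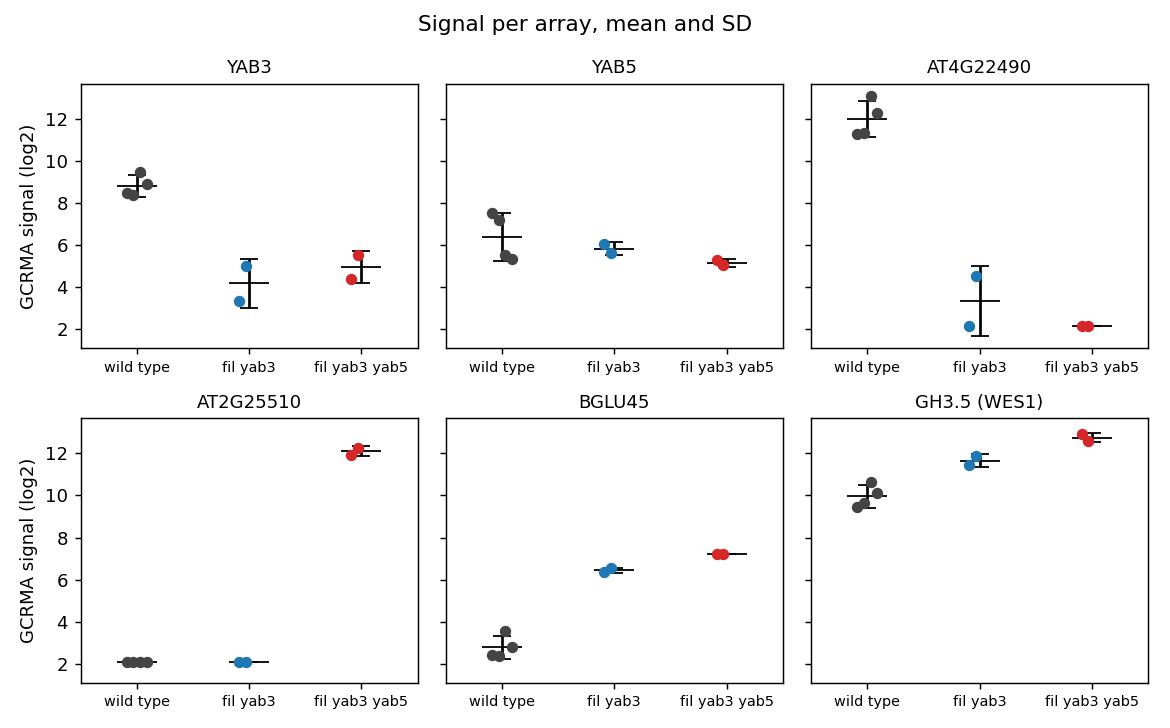
Log2 GCRMA signal (y axis) of 6 genes in each group (x axis); points are arrays, horizontal lines group means and bars the SD. YAB3 lies at 8.35 or above on every wild-type array and at 5.50 or below on every mutant array, while AT2G25510 is at the floor outside the triple mutant.

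The comparison of the double mutant with wild type asks what the loss of FIL and YAB3 changes in the apex. Of the lowered probe sets, 3 name a single gene, YAB3 and 2 genes of the lipid-transfer protein family, which was not tested as a group. AT4G22490 went from 11.98 ± 0.87 to 3.34 ± 1.67, a fall of 8.64 ± 0.74 log2 units (adjusted p = 0.012), and AT5G59330 from 10.13 ± 0.77 to 3.33 ± 0.45, at least 70.0-fold lower (adjusted p = 0.019). Among raised genes, AT1G58025 was at least 43.5-fold higher (adjusted p = 0.012) and AT1G35650 at least 9.56-fold higher (adjusted p = 4.9e-05). AT1G35650 lay near the floor with almost no spread on all wild-type and triple mutant arrays, which lowers its p-value. BGLU45, a beta-glucosidase that acts on lignin precursor glucosides, was at least 5.47-fold higher (adjusted p = 0.014), and 2A6, which resembles 2-oxoglutarate-dependent dioxygenases, rose by 3.40 ± 0.36 (adjusted p = 0.019). AT1G62290, an aspartyl protease, rose from 5.45 ± 0.14 to 8.45 ± 0.03, AT1G35612 by 4.45 ± 0.37 log2 units and AT1G35617 by 3.04 ± 0.33, while AT1G42705 was at least 3.23-fold and AT1G17830 at least 3.02-fold higher. AT1G35650 and AT1G42705 lay near the floor in the triple mutant, which lacks FIL and YAB3 too, so that loss did not raise them in both mutants.

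The fit called 23 of 13888 probe sets in this comparison, 13 raised and 10 lowered, with 964 at an unadjusted p under 0.05. All 9 raised named genes lie on chromosome 1, which holds 26.4% of the named genes tested. Against wild-type arrays 3 and 4 alone 49 probe sets were called, 18 of them among the 23. The count fell to 15 without wild-type array 1, 11 without wild-type array 4, 9 without double mutant array 2 and 0 without double mutant array 1 (limma, 433 at an unadjusted p under 0.05). Genes bright only in the double mutant cannot pass the filter with 1 of its arrays, and on the probe sets tested with all 8 arrays the last counts were 15 and 3. Without double mutant array 1, AT1G35650 and AT1G42705 went untested and the other named genes lost their calls (adjusted p = 0.091 to 0.304); without double mutant array 2 the same held except for AT1G35612 and AT4G22490, which passed. AT1G42705, AT1G35617 and AT1G17830 lost their calls without any 1 wild-type array (0.052 to 0.083), AT5G59330 without wild-type array 2 (0.051) or 4 (0.059), BGLU45 without wild-type array 4 (0.0502), 2A6 without wild-type array 4 (0.059), and 2A6 and AT1G42705 without triple mutant array 1 or 2 (0.057).

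No fixed gene list passed in the double mutant with camera. The 8 photosynthesis genes had a median difference of -0.26 (adjusted p = 0.529), the 6 flavonoid and anthocyanin genes 0.59 (adjusted p = 0.539) and the 4 lamina and margin growth genes -0.31 (adjusted p = 0.539). Against wild-type arrays 3 and 4 these medians were 0.05, 0.15 and -0.27, none past the threshold, and against arrays 1 and 2 the photosynthesis median was -0.54 (adjusted p = 0.028), so its direction rests on those arrays. In the lamina list NGA2 differed by -1.61 ± 0.98 and NGA3 by -0.83 ± 0.47, neither past the threshold. The NGA2 difference was -0.12 against wild-type arrays 3 and 4 (adjusted p = 0.814) and -3.10 against arrays 1 and 2 (adjusted p = 0.0030). The 3 cold and drought response genes, at a median of -0.42 (adjusted p = 0.539), passed without wild-type array 3 (adjusted p = 0.046). Of the 4 auxin response genes, with a median of -0.93 (adjusted p = 0.539), none passed over all genes tested with all wild-type arrays and 2 pass adjusted over the list alone. Their median was -1.53 for the 3 tested against wild-type arrays 3 and 4 (camera adjusted p = 0.206). It was -0.62 against arrays 1 and 2 (camera adjusted p = 0.746). SEU, a co-repressor partner of YABBY proteins, differed by -0.32 ± 0.33 (adjusted p = 0.845).

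The comparison of the triple mutant with wild type asks what is changed when YAB5 is lost as well. AT2G25510 was at the floor in all wild-type arrays and at 12.10 ± 0.22 in the triple mutant, at least 274-fold higher (adjusted p = 7.6e-07). Its chromosomal neighbour AT2G25450, which encodes GSL-OH, an enzyme of glucosinolate side-chain modification, was at least 81.3-fold higher (adjusted p = 1.1e-06), and the TRAF-like gene ZW9 at least 248-fold higher (adjusted p = 8.7e-05). AT2G25510, AT2G25450 and ZW9 lay near the floor with almost no spread in wild type. Their p-values therefore rest on the few arrays that vary and overstate the precision. The jacalin-lectin gene AT1G52100 was at least 46.1-fold higher and AT1G33790, of the same family, rose by 6.34 ± 0.44. AT5G56910 was at least 42.0-fold higher, the TRAF-like gene AT1G65370 at least 34.5-fold, AT3G44430 at least 22.6-fold and the TIR-NBS-LRR gene AT1G63880 at least 13.3-fold. AT1G35612 rose by 5.43 ± 0.37, as it had in the double mutant.

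Among named genes lowered in the triple mutant, AT4G22490 was at least 252-fold lower than in wild type (adjusted p = 0.00062), AT5G59330 fell by 6.77 ± 0.69 (adjusted p = 0.0028) and AT5G55450 was at least 28.3-fold lower (adjusted p = 0.016). AT3G44070 was at least 27.6-fold lower, AT5G55570 at least 12.4-fold, AT1G14580, the zinc finger gene BLUEJAY, at least 10.7-fold, AT5G24240, which encodes a phosphoinositide kinase family member, at least 5.20-fold and AT5G48350 at least 4.39-fold. AT5G15360 fell by 5.08 ± 0.42 log2 units.

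Members of the fixed lists that passed in the triple mutant were few. GH3.5 (WES1), which conjugates auxin to amino acids, rose by 2.80 ± 0.36 to 12.75 ± 0.21 (adjusted p = 0.0081). With all wild-type arrays it was the only one of 4 auxin response genes to pass over all genes tested and also the only one adjusted over the list alone. The auxin list had a median of -0.18 (camera adjusted p = 0.771). For the 3 auxin genes tested against wild-type arrays 3 and 4 the median was -1.59 (camera adjusted p = 0.549), so the rise of GH3.5 does not stand for the list. MUTE, a regulator of stomatal lineage progression, was at least 1.27-fold lower (adjusted p = 0.031); it was the only one of 4 stomatal genes to pass, 2 pass adjusted over the list alone, and all 4 differences were negative, with a median of -1.0 (camera adjusted p = 0.074, and adjusted p = 0.518 with an estimated correlation; 0.0020 without triple mutant array 2). EXPA9, of the cell wall loosening expansins, was at least 1.24-fold higher (adjusted p = 0.048), the only one of the 5 listed alpha-expansins tested to pass; EXPA20, outside the list and chosen after its values were seen, was at least 3.64-fold higher (adjusted p = 0.011). GH3.5 lost its call without triple mutant array 1 (adjusted p = 0.136) or array 2 (0.111), MUTE without any 1 array but wild-type array 3 (0.060 to 0.326) and EXPA9 without any 1 array outside the triple mutant (0.063 to 0.091); without either triple mutant array EXPA9 was too dim to be tested. The gibberellin receptors GID1A and GID1B differed by 1.44 ± 0.38 (adjusted p = 0.090) and 1.56 ± 0.37 (adjusted p = 0.066). Photosynthesis genes had a median of -0.22 (adjusted p = 0.359) and trichome genes one of -1.37 (adjusted p = 0.146). Against wild-type arrays 3 and 4 these medians were 0.08 and -0.55 and that of stomatal genes -1.04 (adjusted p = 0.834, 0.455 and 0.455), while against arrays 1 and 2 photosynthesis and trichome genes passed, at -0.51 and -1.57 (adjusted p = 0.049 for each). The 5 alpha-expansins had a median of 0.95 (camera adjusted p = 0.354) with all wild-type arrays. The 4 tested against arrays 3 and 4 had a median of -0.12 (adjusted p = 0.952), so the direction depended on the wild-type arrays and genes used. With all wild-type arrays no list passed with camera, and 2 lists, stomatal genes and alpha-expansins, passed with limma's fry (adjusted p = 0.023 and 0.010).

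The fit called 538 probe sets in the triple mutant against wild type, 308 raised and 230 lowered. Against wild-type arrays 3 and 4 alone it called 1265, of which 483 were among the 538, with 566 raised and 699 lowered. The count fell to 46 without triple mutant array 1 and 47 without array 2 (122 and 129 on the probe sets tested with all 8 arrays, since 66 and 67 of the called probe sets no longer pass the filter), to 317 without wild-type array 1, 353 without wild-type array 4, 303 without double mutant array 1 and 299 without double mutant array 2. AT5G55450, AT5G55570 and AT1G14580 lost their calls without triple mutant array 1 (adjusted p = 0.171, 0.142 and 0.066) or array 2 (0.193, 0.135 and 0.095), where AT2G25510, AT2G25450, AT1G52100, AT3G44430, AT5G56910, AT1G65370 and AT1G63880 went untested.

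The mutants were compared with each other on shared changes. Of the 23 probe sets called in the double mutant, 18 were called in the triple mutant in the same direction, 9 raised and 9 lowered, and none in opposite directions. Against wild-type arrays 3 and 4 alone 43 were called in both, 17 raised and 26 lowered. Independent lists of these sizes would share 0.288 raised and 0.166 lowered probe sets. In 100 simulations, unchanged mutants shared simulated wild-type arrays with independent noise, which leaves out the wild-type pairs. No probe set was called in both there. With nothing changed almost none can pass the threshold, so this does not measure how many calls shared controls give. Fold changes against wild type correlated across probe sets with r = 0.704, against 0.338 in the simulations, and their covariance was 0.391 against 0.0957. A shift between the wild-type pairs, which both comparisons share, is missing from the simulated values, so they may be too low. With the wild-type arrays split so that each mutant had its own 2, r ranged from 0.068 to 0.648 over the 6 assignments. It was lowest, at 0.068 and 0.117, where the mutants were set against different pairs, with covariances of 0.0525 and 0.102. In the other assignments, at 0.552 to 0.648, each mutant had 1 array of each pair. There the shift between the pairs still entered both differences, so these values may be too high. These correlations are across probe sets, which are not independent replicates. The count of 18 fell to 0 without double mutant array 1 and 8 without array 2 (1 and 11 on the probe sets tested with all 8 arrays), to 9 without wild-type array 4 and to 11 without triple mutant array 1.

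**Figure D3:**
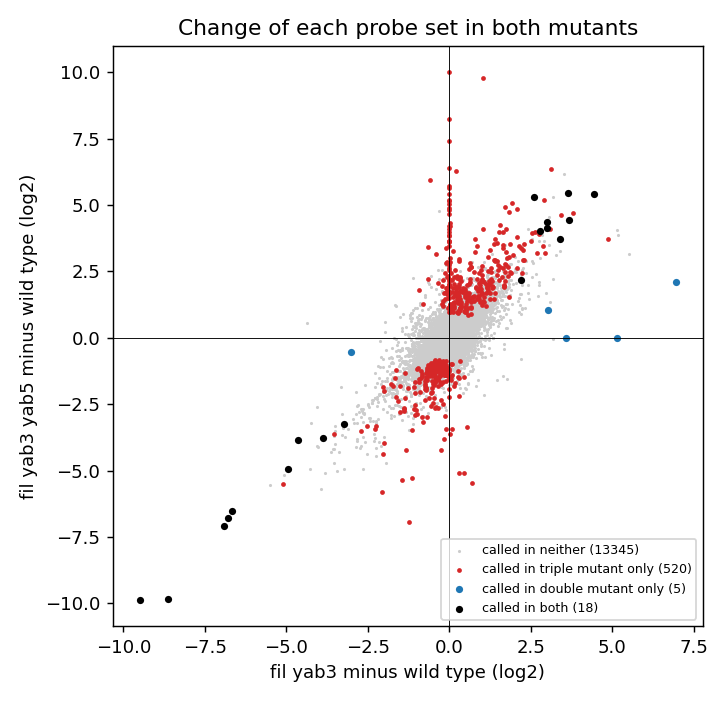
Log2 difference from wild type of each tested probe set in the double mutant (x axis) and the triple mutant (y axis), coloured by where it was called. The 18 probe sets called in both lie in the lower left and upper right, and most of those called in the triple mutant only lie within 1 log2 unit of 0 on the x axis.

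The triple mutant was compared with the double mutant, from which it differs by label in YAB5. Among named genes the largest rises were in genes with a mean log2 signal below 4 in the double mutant. AT2G25510 was at least 274-fold higher in the triple mutant (adjusted p = 2.2e-06), AT2G25450 at least 81.3-fold (adjusted p = 3.1e-06), AT1G52100 at least 46.1-fold and AT1G65370 at least 34.5-fold, and ZW9 rose by 8.75 ± 0.58. The floor lowers the p-values of AT2G25510 and AT2G25450 here too. AT3G44070 was at least 45.1-fold lower in the triple mutant, AT1G35650 at least 9.56-fold and AT5G24240 at least 4.38-fold. AT5G15360 fell by 5.38 ± 0.48 and AT1G58025 by 4.87 ± 0.70, so that AT1G35650 and AT1G58025, both raised in the double mutant, were lower in the triple mutant. YAB3 and YAB5 differed by 0.78 ± 0.64 and -0.67 ± 0.76 (adjusted p = 0.936 and 0.990).

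The fit called 94 probe sets between the mutants, 76 raised and 18 lowered in the triple mutant. With only wild-type arrays 3 and 4 in the fit it called 143, 98 raised and 45 lowered, and with array weights 284, 152 raised and 132 lowered, so the share raised depends on the fit. The trichome list, SIM, TRY and GIS, was lower by a median of 1.19 with camera (adjusted p = 0.0117). It did not pass with an estimated correlation (adjusted p = 0.280) or with fry (adjusted p = 0.076). In this fit none of the 3 passed singly, 2 adjusted over the list alone. GIS lay at 5.4 and 5.7 on the double mutant arrays and at 3.5 and 3.4 on the triple mutant arrays. On the wild-type arrays it lay at 4.4, 4.3, 3.4 and 3.4, so its difference includes a higher signal in the double mutant. TRY lay at 3.4 on both triple mutant arrays, below the log2 value of 4 of the filter. Alpha-expansins had a median difference of 0.89 (camera adjusted p = 0.070, and adjusted p = 0.017 with fry). Stomatal genes had one of -0.71 (camera adjusted p = 0.070). Fewer probe sets were called without an array of either mutant, 11 without either triple mutant array (62 and 66 on the probe sets tested with all 8 arrays) and 57 and 63 without double mutant arrays 1 and 2. AT1G58025 lost its call without any 1 array outside the triple mutant (adjusted p = 0.060 to 0.205), AT3G44070 without triple mutant array 1 (0.074) or 2 (0.061) and AT5G24240 likewise (0.061 and 0.059). Without double mutant array 2 the trichome list did not pass (adjusted p = 0.056), and without triple mutant array 2 it passed with 3 further lists, stomatal, cold and drought response, and flavonoid and anthocyanin genes. On the probe sets tested with all 8 arrays only 2 lists passed there.

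Calls between the mutants were set against position in the genome. Within 150 loci of YAB5 in gene order, 2 of 72 tested genes were called, AT2G25450 and AT2G25510, against 56 of 7176 away from the mutated loci (Fisher's exact test, two-sided, p = 0.113). Around FIL 0 of 76 and around YAB3 0 of 26 were called. Over the 3 windows together the odds ratio was 1.48 (exact 95% interval 0.173 to 5.68, p = 0.401).

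**Figure D4:**
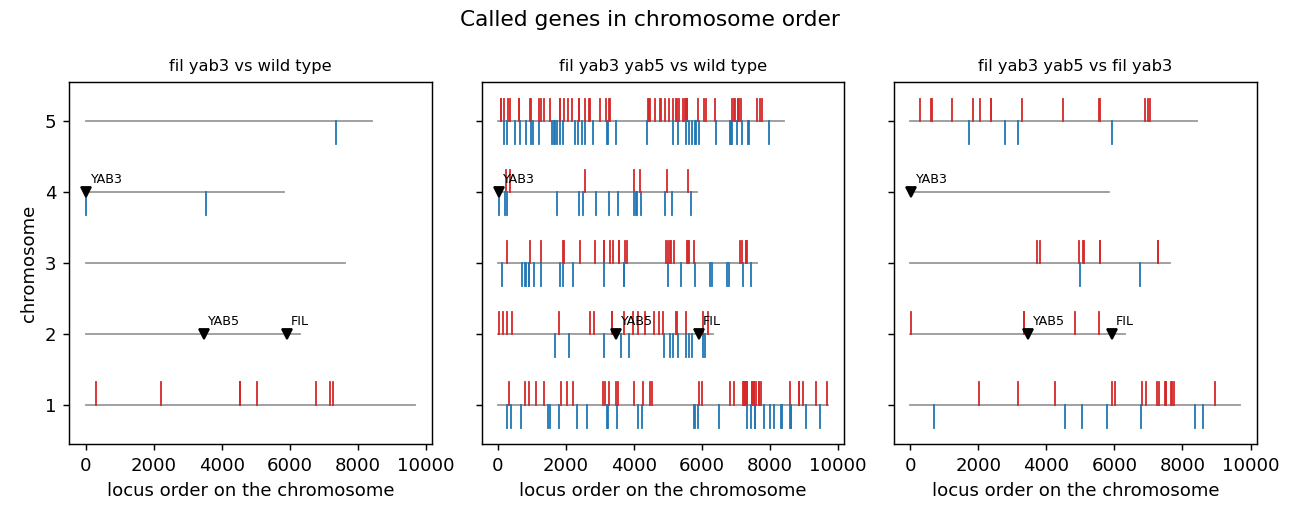
Genes called in each comparison along chromosomes 1 to 5 (y axis) in locus order (x axis), with marks above the line for higher and below for lower in the first-named group; triangles show FIL, YAB3 and YAB5. The 9 raised genes of the double mutant all lie on chromosome 1.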

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

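All tests of explanations in this part were chosen after the result was seen. Among the 4 wild-type arrays, the highest or lowest value stood off for 12 of 77 named genes that varied. Independent, normally distributed values would give about 1 in 20. Here the arrays form pairs and the anthocyanin genes moved together. AT1G58025, AT1G52100 and AT5G15360 passed only because the other arrays hold tied values. The number of such genes is therefore no measure of an excess. Anthocyanin genes stood highest on wild-type array 4, with UF3GT at 9.55 against a mean of 6.51 on the other 3 arrays, DFR at 11.32 against 8.60 and the malonyltransferase AT5MAT at 6.67 against 3.57. The same genes differed between the triple mutant arrays, with DFR at 7.51 on array 1 and 11.06 on array 2. COR15B, a cold-regulated gene, was low on wild-type array 3 at 4.25 against 6.84. EXPA16 stood off at 4.52 on array 2 against 2.39. Values that differ little or lie near the floor were AT1G58025 at 2.15, AT1G35617 at 3.77, AGO7 at 4.75, AT1G52100 at 2.11, AT5G56910 at 2.56, AT5G15360 at 10.19 and EXPA9 at 3.47.

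An Affymetrix control probe set left out of the comparisons, U12639, was near the floor on all wild-type arrays, with a mean of 2.18, and bright on all mutant arrays, the lowest of which exceeded the highest wild-type array by 6.86 log2 units. What it detects is not given in the sources used here.

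Wild-type arrays 1 and 2 stood apart from the other 6 arrays. Spike-ins hold no plant RNA, and 100% of them were higher on both arrays than on all others, which fits another labelling or hybridisation batch. Wrong genotype labels are argued against by YAB3, which on these arrays lay at least 2.85 log2 units above every mutant array, and more mature tissue as the whole cause by the spike-in difference of 2.73 log2 units. More mature tissue may still add to the split, and the nuclear photosynthesis genes were higher there by a median of 0.571 (camera adjusted p = 0.020, and adjusted p = 0.492 with an estimated correlation). The wild-type pairs differed at 3366 probe sets.

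The triple mutant called more probe sets than the double mutant. Lower RNA quality of double mutant array 1 is argued against as the cause, since with 1 array left per mutant the triple mutant still called at least 46 and the double mutant with array 2 alone called 0 (122 and 3 on the probe sets tested with all 8 arrays). That the same genes move less far in the double mutant stayed open: with split wild-type arrays, 50.6% to 73.1% of triple mutant calls moved the same way in the double mutant. Where the split followed the 2 wild-type pairs the shares were 50.6% and 51.7%, close to what random directions would give. The median ratio of the double to the triple mutant difference was 0.0019 and 0.012 there, and 0.12 to 0.21 in the other splits. The shift between the pairs enters the 2 differences unlike in the former splits and alike in the latter, so neither kind can decide. The added loss of YAB5 remains an untested biological explanation.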

How the results depend on the processing

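Fits with other wild-type arrays, and fits without 1 array on the probe sets tested with all 8, were chosen after seeing the data. Counts are given for the double mutant, the triple mutant (each against wild type) and the mutants against each other, with 23, 538 and 94 in the chosen fit. With no filter the first and last were 12 and 144, and only 4 of these 12 were among the 23. Of the 430 called in the triple mutant with no filter, 303 were among the 538. Without wild-type array 3, 17 of the 26 called in the double mutant were among the 23. With a filter at a log2 value of 6 the last count was 55, with array weights the last 2 were 1826 and 284, and with only the groups compared all were 14, 305 and 53. Against wild-type arrays 3 and 4 they were 49, 1265 and 143, against arrays 1 and 2 they were 1790, 3366 and 149, and with the wild-type pairs as separate groups 332, 2484 and 233. The replicate block gave 950, 2500 and 74; wild-type arrays 3 and 4 have no partner of their number, so this fit sets the mutants against arrays 1 and 2. The numbers did not pair the samples, with correlations of deviations of -0.097, -0.054 and 0.0039. Leaving out each array gave 0 to 26, 46 to 578 and 11 to 94, a lone array being assumed to vary like the other groups. On the probe sets tested with all 8 arrays the ranges were 3 to 26, 122 to 571 and 61 to 92.

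The 18 shared calls became 5 with no filter, 845 with the replicate block, and 43, 1513 and 307 with the 3 choices of wild-type arrays, and 0 to 23 with each array left out. The correlation of 0.704 became 0.851 with the replicate block and 0.852 against wild-type arrays 1 and 2, and 0.609 to 0.765 with each array left out. Lists called were 0, 0 and 1. They became 1 in the double mutant with the replicate block or wild-type arrays 1 and 2, and in the triple mutant 1 with no filter, 2 with fry and 2 against arrays 1 and 2. Between the mutants 0 were called with an estimated correlation or the filter at 6. With fry 1 was called there, alpha-expansins and not the trichome list. Leaving out each array gave 0 to 1, 0 to 1 and 0 to 4. The odds ratio near the mutated loci, 1.48, turned to 0 with windows of 75 loci and 0.786 with 300, where no window passed. Fitting the wild-type pairs as separate groups raised all 3 counts of probe sets called, so the shift between the pairs lowers them in the chosen fit. Leaving out a double mutant array does not touch the difference of the triple mutant from wild type. That count changed there through the filter, the estimated spread and the adjustment. The causes of the other changes were not tested. Quantile normalization, median centring, the intensity trend and removal of probe sets matching several genes kept all these counts within 1.5 times. Quantile normalization and median centring could change little, since GCRMA already normalizes by quantiles and the array medians were close. No named gene that passed changed sign; where tested, calls were lost in 63 of 233 settings over the 12 called genes of the double mutant, 31 of 441 over 23 of the triple mutant and 18 of 189 over 10 between them.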

Other observations

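The genes of this paragraph were chosen after their values were seen, and the tests of explanations in this part, except the window around YAB5, were chosen after the result was seen. Of the genes called in the triple mutant against wild type, 47 carry a symbol of their own, 32 raised and 15 lowered, and 44 were also called against wild-type arrays 3 and 4 alone. Several lowered genes act in chloroplasts: HCF101, which assembles iron-sulphur clusters, fell by 1.46 ± 0.17 (SE), the peptide deformylase PDF1B by 1.42 ± 0.28, the chaperonin subunit Cpn60beta4 by 1.39 ± 0.25, the magnesium chelatase subunit CHLI2 by 1.25 ± 0.22, NOL, which acts in chlorophyll b breakdown, by 1.22 ± 0.23 and the plastid division gene FTSZ2-2 by 1.12 ± 0.23. Whether chloroplast genes are over-represented was not tested.

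Raised genes chosen in the same way, as a group not tested for over-representation, included the auxin-conjugating enzyme gene GH3.17. It rose by 2.43 ± 0.49 (adjusted p = 0.044, and 0.053 against wild-type arrays 3 and 4), the endoglucanase GH9B13 by 2.08 ± 0.36 and the amine oxidase CuAO1 by 3.72 ± 0.51. The expansin EXPA20 was at least 3.64-fold higher and CCR2, a cinnamoyl-CoA reductase, at least 5.58-fold. APS4, an ATP sulfurylase, rose by 2.91 ± 0.45 and the glucosinolate transporter GTR2 by 1.68 ± 0.30. SLY2, an F-box gene of gibberellin signalling, was at least 7.93-fold higher.

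Of the added families, the chlororespiratory reduction genes, which act on the plastid NDH complex, were lower in the triple mutant, with all 5 differences negative and a median of -0.96 (camera adjusted p = 0.032, and adjusted p = 0.809 with an estimated correlation), though none passed singly; against wild-type arrays 3 and 4 the median was -0.42 (adjusted p = 0.114). Between the mutants all 5 were lower in the triple mutant, by a median of 1.06 (adjusted p = 0.064, and adjusted p = 0.642 with an estimated correlation), with adjusted p = 0.0057 when only wild-type arrays 3 and 4 were in the fit and 0.012 with only arrays 1 and 2. No other family passed in any of the 3 comparisons.

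The positions of called genes were examined for gathering on the chromosomes. In the triple mutant 35 probe sets were above a log2 value of 6 on both arrays and at or below 4 on all wild-type arrays, as segments of another accession carried along with the mutations could produce, and 22 of them name a gene. Of these 22, 27.3% had another such gene 6 to 100 loci away, against a mean of 11.4% in random sets (one-sided permutation p = 0.105, and p = 0.155 against other raised genes), and the window around YAB5 gave p = 0.113, so too few genes keep linked segments open. The 9 raised genes of the double mutant, 6 loci when neighbours within 100 loci are counted once, all lay on chromosome 1 (exact multinomial p = 0.000626 for any 1 chromosome), a pattern seen in these genes before it was tested on them. Of 3 further loci raised only against wild-type arrays 3 and 4, 0 lay there (exact binomial p = 1, one-sided), too few to decide, so a response that does not depend on position stays open.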
